A study of Saccharomyces cerevisiae and Saccharomyces x bayanus and Nakaseomyces glabratus with 4 samples.

How the data were processed

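Nucleosomal DNA was sequenced from 4 yeast species, with 1 library each of Saccharomyces cerevisiae (strain BY4741), Saccharomyces bayanus (NRRL Y-11845), Candida glabrata (CBS138) and Saccharomyces kudriavzevii (IFO 1802). Per the labels' protocols, cells were grown in rich glucose medium to mid-log phase and fixed with formaldehyde. Spheroplasts were then digested with micrococcal nuclease (MNase), an enzyme that cuts DNA between nucleosomes, and DNA of mononucleosome size was cut from a gel and sequenced on the Illumina GAII. Per the labels, replicates were made for 3 species. A single file per species was used here, and whether it pools replicates is not given in the sources used here. The aligner, genome build, annotation and any shift of the reads are also not given in the sources used here.

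Each deposited file gives, for every gene, an ID and 1601 whole-number read counts, 1 per base. The deposited counts were not divided by library size. The values themselves show what the positions are. In S. cerevisiae, 2390 windows matched a gene in the reference table and ended early. Of these, 2135 (89.3%) ended at a length equal to the gene's length from start to end plus 600 positions. A window therefore runs from 600 bp upstream of the first base of the start codon (position 0) to 1000 bp downstream, and stops at the end of the gene. Positions have no strand, and windows of neighbouring genes overlap, so a read can enter more than 1 window. Gene names, gene lengths (from the start and end coordinates) and neighbours of S. cerevisiae came from the RefSeq table of assembly R64. It named 5777 IDs and left 625 unmatched. The files of the other species do not pair their IDs with names, so no orthologs were compared.

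Total counts in the windows were 22283726 in S. cerevisiae, 24180974 in S. bayanus, 24344881 in C. glabrata and 4478977 in S. kudriavzevii. Every window with at least 20 counts between 500 bp upstream and 500 bp downstream was used. The depth of the depleted region was the mean density of the 200 bp upstream of the start codon over that of the 500 bp downstream. Its minimum and the nucleosome peaks were read from the mean profile smoothed over 25 bp, and spacing was the slope through the first 4 peaks. Width was taken at the midpoint between the minimum and the downstream mean. The second nucleosome was taken as the highest point from 80 to 220 bp, a range chosen after the profiles were seen. The nucleosome repeat length was the slope through the first 4 peaks of the autocorrelation of counts, smoothed over 15 bp, in genes with values to 1000 bp.

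The repeat length was at first computed over the whole window. Windows were simulated with the number, depth and missing positions of each species, and arrays of known spacing on both sides of a depleted gap. On these, that version came out 4.1 to 7.5 bp too short. The simulated array and gap were the same for all 4 species and were not fitted to their profiles. The simulation therefore does not show how short that version is in a given species. The same simulated arrays of S. cerevisiae depth without a gap gave an error of 0 bp, so the shortening in the simulation came from the gap. The whole-window version was replaced by the autocorrelation from the start codon on. This recovered the simulated spacings with an error of 0 bp at the depth of each of the 4 species. The change was made after both sets of values had been seen on the real libraries. It changes which species stands farthest from S. cerevisiae, and both sets are given. In the same simulation the spacing of the profile peaks was within 1 bp and the upstream-to-downstream ratio within 0.0065 of the truth.

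With 1 library per species there was no test between species, and species, library and assembly cannot be told apart. Spread is given as the SD over 10 sets of genes, made of consecutive IDs within a library. It is a spread within a library and not replicate error. The design had planned chromosomes or contigs for this purpose, which the files do not name. Each set holds only part of the genes, so this SD is wider than gene sampling alone would give for a whole library. An SD of the difference combines the SDs of 2 libraries without scaling them to whole libraries. A small number of these SDs therefore does not show that 2 libraries are alike. For S. cerevisiae genes, the log2 density of the 200 bp upstream over the library mean was computed with an exact Poisson 95% interval, which covers counting error only, and a gene with 0 counts was set at 3 counts. The 16 gene lists were fixed before the data were examined. Each list's median was placed among 10000 random lists of the same size matched on downstream density in 20 bins, over 5764 protein-coding genes. Percentiles of the downstream density used random lists drawn from all of these genes without matching. This percentile describes the library and is not a p-value. Lists below percentile 2.5, or as far above the middle, are called outside the random range. Of 200 simulated random lists of 60 genes, drawn from 6397 S. cerevisiae genes rather than these 5764, 4.5% fell outside, and 99.5% did so after being lowered by 0.5 on the log2 scale. With lists of 20 genes these shares were 3.5% and 80%. Counts of 6397 S. cerevisiae genes were also simulated, drawn from a Poisson distribution. The median log2 change recovered was -1.95 for a 0.25-fold change and 1.01 for a 2-fold change. The intervals covered the truth for 95.6% of the 6197 genes left unaltered, but for 88% of the 50 genes lowered to 0.25-fold. The intervals assume the same distribution, so this does not test whether the real counts follow it.

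Genes named were the 5 lowest and 5 highest upstream densities, the extremes and the middle of each list, and a set of landmark genes, by a rule fixed before the data were examined. A second group of lowest and highest genes was chosen after the values were seen. It came from 5619 genes without stretches of 100 positions at 0 and with a downstream log2 density above -1. These 5619 genes were not drawn from all IDs. Alternatives covered the windows, smoothing, depth, a cap of 1 read per position and the choice of IDs. Fragment length, read shifts, ortholog differences, base composition and reads on mitochondrial or multicopy DNA were not analysed here. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.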

Results

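Nucleosome positions around gene starts were compared between 4 yeasts grown in the same rich medium: S. cerevisiae, its relatives S. bayanus and S. kudriavzevii, and the more distant C. glabrata, an opportunistic pathogen. MNase leaves the DNA wrapped in nucleosomes, so read counts follow nucleosome occupancy. The files held 6402 gene windows for S. cerevisiae, 4731 for S. bayanus, 4687 for C. glabrata and 3403 for S. kudriavzevii. Mean depth was 2.53 counts per position in S. cerevisiae, 3.47 in S. bayanus, 3.50 in C. glabrata and 0.914 in S. kudriavzevii, the shallowest library. There was 1 library per species and no replicate value. Errors are SDs over 10 sets of genes within a library, and a difference between species has no replicate check.

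All 4 species had a nucleosome-depleted region just upstream of the start codon, followed by a regular array of nucleosomes into the gene. Density in the 200 bp upstream, relative to the 500 bp downstream, was 0.657 ± 0.011 in S. cerevisiae, 0.647 ± 0.018 in S. bayanus, 0.602 ± 0.019 in S. kudriavzevii and 0.577 ± 0.024 in C. glabrata. The S. cerevisiae value depended on which IDs were counted. The 5777 IDs found in the reference table gave 0.628 ± 0.0099, and the 625 others had hardly any depletion, at 0.957. Relative to the matched S. cerevisiae genes, the difference was -2.0 SD of the difference for C. glabrata, -1.2 SD for S. kudriavzevii and 0.91 SD for S. bayanus. The lowest point lay at -127 ± 18 bp in S. cerevisiae, -136 ± 9.0 bp in S. bayanus, -130 ± 19 bp in S. kudriavzevii and -178 ± 21 bp in C. glabrata.

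**Figure D1:**
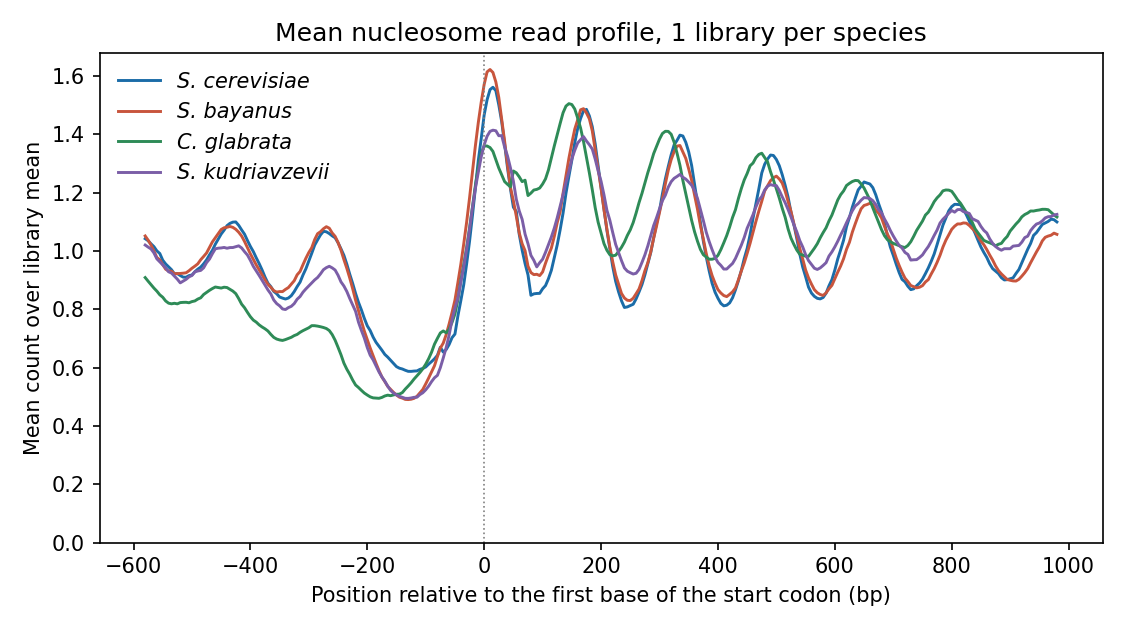
Mean count over the library mean (y axis) by position relative to the start codon in bp (x axis), smoothed over 25 bp, with 1 line per species. The C. glabrata line stays low upstream of the depleted region, and its second peak lies at 146 bp against 168 to 172 bp in the other species.

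C. glabrata differed from the other species farther upstream and, as given below, also within genes. Between 600 and 400 bp upstream, its density was 0.697 ± 0.025 of the downstream level, against 0.892 ± 0.018 in S. cerevisiae, 0.889 ± 0.013 in S. bayanus and 0.846 ± 0.011 in S. kudriavzevii. The difference of C. glabrata from S. cerevisiae was -6.4 SD of the difference, and -6.0 SD from its matched genes. Measured against the downstream mean, the low region was 384 ± 20 bp wide in C. glabrata and 182 ± 5.8 bp in S. cerevisiae. The level at which that width was taken in C. glabrata, 0.702 of the downstream mean, was close to the level of its flank, so the width there includes part of the flank and is not the distance between flanking nucleosomes.

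Within genes, the first nucleosome peaked at 14 ± 4.2 bp in S. cerevisiae, 11 ± 3.7 bp in S. bayanus and 26 ± 8.8 bp in S. kudriavzevii. In C. glabrata a weak first peak lay at 3 bp. With 51 bp smoothing these positions were 14, 11, 13 bp and, in C. glabrata, 10 bp, so the later S. kudriavzevii position depended on the smoothing. In 2 of the 10 sets of C. glabrata genes the first peak was missed and counting began at the next nucleosome. In 1 more C. glabrata set the first peak found lay at 52 bp, near a narrow spike at 58 bp. The SDs of C. glabrata peak heights and peak spacing include these slips. The second nucleosome, taken as the highest point from 80 to 220 bp, lay at 172 ± 3.4 bp in S. cerevisiae, 168 ± 2.2 bp in S. bayanus, 170 ± 4.1 bp in S. kudriavzevii and 146 ± 7.4 bp in C. glabrata. The first peak stood over the following trough by 0.650 ± 0.066 of the downstream mean in S. cerevisiae, 0.629 ± 0.094 in S. bayanus, 0.430 ± 0.11 in S. kudriavzevii and 0.158 ± 0.11 in C. glabrata. Peaks flattened with distance from the start codon in S. cerevisiae, from 0.650 at the first to 0.442 at the fourth, in S. bayanus, from 0.629 to 0.363, and in S. kudriavzevii, from 0.430 to 0.257. In C. glabrata the second peak was the highest at 0.430, and the fourth stood at 0.290. The end of the gene was measured in genes of at least 400 bp whose windows ended early. These were 1815 genes in S. cerevisiae, 1409 in S. bayanus, 1419 in C. glabrata and 1205 in S. kudriavzevii. In the last 100 bp of the gene, density relative to 200 bp farther in was 1.06 ± 0.061 in S. cerevisiae, 1.05 ± 0.053 in S. bayanus, 1.02 ± 0.043 in C. glabrata and 1.01 ± 0.045 in S. kudriavzevii. There was no drop up to the gene end, and positions beyond it were not in the windows.

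**Figure D2:**
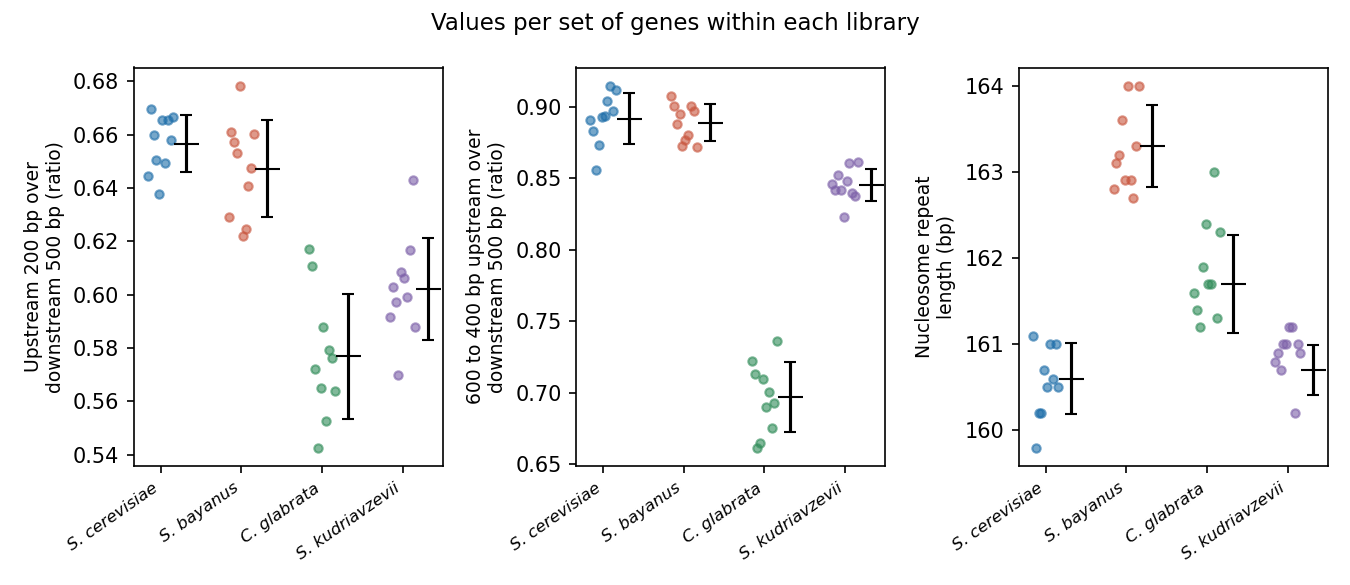
Upstream ratio, ratio farther upstream and repeat length in bp (y axes, which do not start at 0) for the 4 species (x axes). Points are the 10 sets of genes within a library, and the bar with whiskers is the whole library ± SD over those sets. C. glabrata lies lowest in the middle panel at 0.697, and S. bayanus highest in the right panel at 163.3 bp.

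Measured from the start codon on, the distance from one nucleosome to the next was longest in S. bayanus. The repeat length downstream of the start codon was 163.3 ± 0.47 bp in S. bayanus, 161.7 ± 0.56 bp in C. glabrata, 160.7 ± 0.29 bp in S. kudriavzevii and 160.6 ± 0.41 bp in S. cerevisiae. S. bayanus exceeded S. cerevisiae by 2.7 bp, or 4.3 SD of the difference, C. glabrata by 1.1 bp (1.6 SD) and S. kudriavzevii by 0.1 bp (0.20 SD). The spacing of the profile peaks was less precise, at 163.2 ± 2.1 bp in S. bayanus, 160.2 ± 2.0 bp in S. cerevisiae, 158.4 ± 5.6 bp in C. glabrata and 156 ± 5.7 bp in S. kudriavzevii, and the largest difference from S. cerevisiae was 1.03 SD, in S. bayanus. Over the whole window, a version that came out too short on simulated arrays, the excess over S. cerevisiae was 3.0 bp (4.1 SD) in C. glabrata and 2.3 bp (2.6 SD) in S. bayanus. In that version C. glabrata was the longest, at 159.6 bp against 158.9 bp in S. bayanus. The size of the C. glabrata excess, and which species was longest, therefore depended on the version used.

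**Figure D3:**
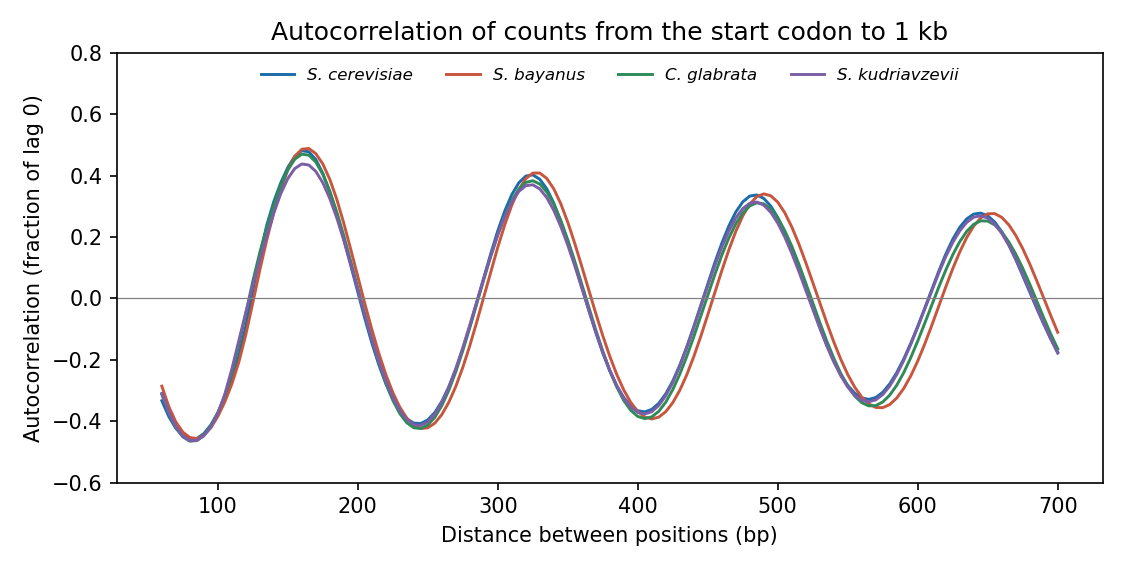
Autocorrelation of counts from the start codon on, as a fraction of its value at distance 0 (y axis), by distance in bp (x axis), with 1 line per species. The S. bayanus peaks fall at increasingly longer distances than those of the other species, in keeping with its repeat length of 163.3 bp.

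In S. cerevisiae, where genes have names, 5 of the 16 lists had emptier upstream regions than matched random lists: glycolysis, both kinds of ribosomal protein, ribosome biogenesis and the proteasome. Log2 upstream density over the library mean had a median of -0.49 over all 5764 protein-coding genes. The 19 glycolysis and fermentation genes had a median of -1.24, with 15 below the median of all genes. Pyruvate kinase CDC19 was lowest at -2.08, phosphoglycerate mutase GPM1 was at -1.24 and glucokinase GLK1 highest at 0.29. The list lay at percentile 0.015 of random lists. With at most 1 read counted per position it was at percentile 10.9, inside the random range.

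The 73 mitochondrial ribosomal protein genes had a median of -1.06, with 53 below that of all genes, from MRPL17 at -3.23 to MRPL38 at 0.68. No random list of 10000 was lower, but with an upstream window of 400 bp the list was at percentile 7.28. The 62 ribosome biogenesis genes, which build ribosomes in the nucleolus, had a median of -0.98, with 49 below, from EBP2 at -2.98 to RRP14 at 0.01. Again no random list was lower, but with the 400 bp window the list was only 0.16 below all genes, against 0.49, at percentile 0.69. The 32 proteasome genes had a median of -0.86, with 25 below, from RPN13, a ubiquitin receptor, at -2.30 to PUP3, a core subunit, at 0.56. Their percentile was 0.98, and 6.99 with the 400 bp window.

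The 135 cytosolic ribosomal protein genes were only slightly emptier upstream, at a median of -0.65 with 80 below that of all genes, from RPL8B at -2.49 to RPL43B at 0.47. Their percentile of 1.58 became 3.65 without genes holding a stretch of 100 positions at 0. With at most 1 read per position the direction turned, and the list stood 0.12 above all genes, at percentile 79.9. Their coding parts also had a low density, with a median of 0.04 over the first 500 bp against 0.18 for all genes. None of the random lists drawn from all genes without matching was lower. The glycolysis list (0.02, percentile 1.78) and the 28 meiosis and sporulation genes (0.0047, percentile 0.27) were low there as well.

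In the main setting, stress response genes had the fullest upstream regions of the 16 lists. The 28 genes had a median of -0.11, with 25 at or above the median of all genes, at percentile 99.95. XBP1, a stress-induced transcriptional repressor, was highest at 0.98, the Hsp70 chaperone SSA4 was at -0.13 and DDR2 lowest at -0.91. This list stayed outside the random range with the 400 bp window (percentile 99.9), with at most 1 read per position (98.9) and without genes holding unread stretches (99.96), but not the first place. Relative to all genes, galactose use stood higher with the 400 bp window (0.30 against 0.27), and so did the phosphate (0.25) and cell wall (0.22) lists with at most 1 read per position (0.20 for stress response). The 43 genes of the tricarboxylic acid cycle and respiratory chain came next, at -0.33 with 32 at or above the median of all genes, from ATP15 at -2.11 to FUM1 at 0.43, and at percentile 96.3 were inside the random range.

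**Figure D4:**
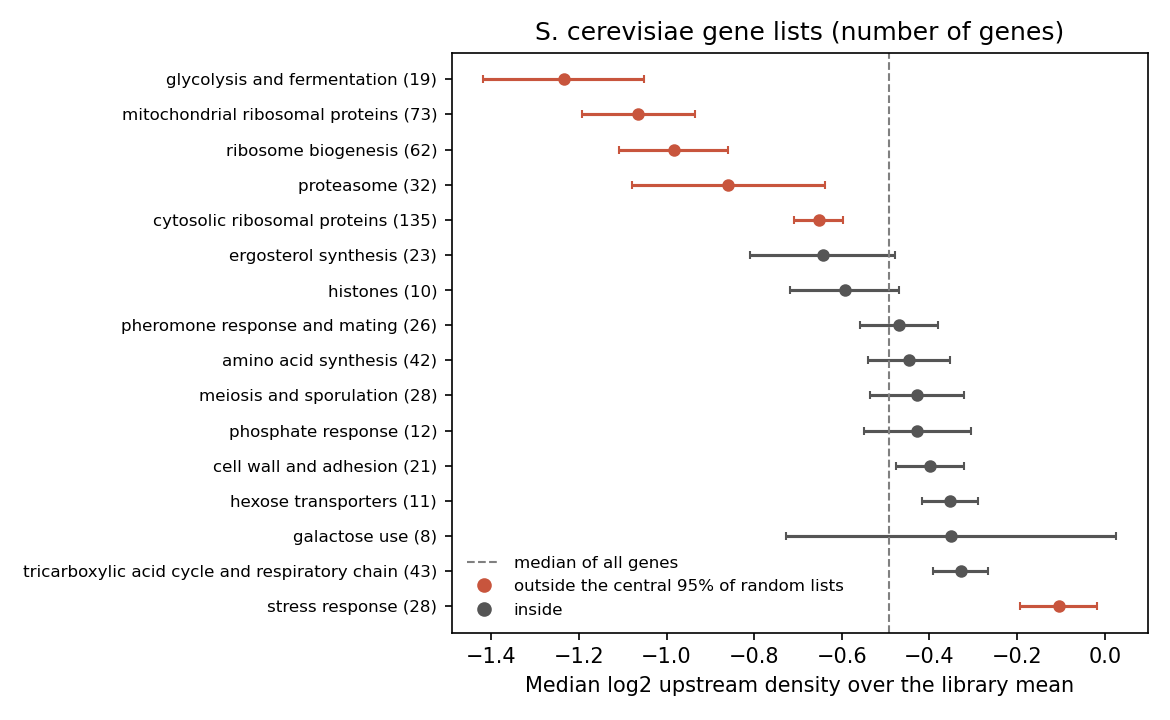
Median log2 upstream density over the library mean (x axis) of the 16 S. cerevisiae gene lists (y axis, number of genes in brackets). Whiskers are bootstrap SDs of the median, the dashed line is the median of all genes at -0.49, and coloured points are the 6 lists outside the central 95% of random lists.

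The other 9 lists were inside the random range. Hexose transporters had a median of -0.35, galactose use -0.35, cell wall and adhesion -0.40, phosphate response -0.43, meiosis and sporulation -0.43, amino acid synthesis -0.45, pheromone response and mating -0.47, histones -0.59 and ergosterol synthesis -0.64. Within galactose use, the activator GAL4 was at -1.74 and its repressor GAL80 at 0.74. With the 400 bp window, the pheromone list (percentile 0.1) and the ergosterol list (1.06) were low and the galactose list (98.2) was high. With at most 1 read per position, the phosphate list (98.0) and the cell wall list (99.5) were high.

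Genes often used to study promoters covered a wide range. The glycolytic TDH3 was at -1.77 (95% interval -2.02 to -1.54), the ribosomal protein gene RPL3 at -1.42 and alcohol dehydrogenase ADH1 at -1.06. GAL1, which is repressed in glucose, was at -0.60, and GAL10, which shares its promoter, at -0.20. The phosphatase gene PHO5 was at -0.17 (interval -0.31 to -0.04) and the phosphate transporter PHO84 at -0.59. The cyclin gene CLN2 was at -0.13, the heat-shock gene HSP12 at -0.51, the histone gene HTA1 at -0.53 and the flocculin gene FLO1 at -0.50. FLO1 held a run of 139 positions at 0 and had a downstream log2 density of -1.52, so it is uncertain. HIS3 was at -2.43 and had no reads from 345 to 464 bp into the gene. BY4741 carries the partial deletion his3Δ1, so HIS3 is uncertain. CUP1-1 and URA3 were not analysed here.

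The 5 lowest upstream densities were at YIL082W and YCR038W-A, each with 0 counts and at least 169-fold below the mean by a floor of 3 counts, YMR045C and YMR046C with the same 14 counts, and COS8 with 19. Each window held a run of 114 or more positions at 0, so these genes are uncertain. Among the 5619 genes without such runs and with a downstream log2 density above -1, both chosen after the values were seen, the lowest were SAM37, for import into the mitochondrial outer membrane (-3.49, 45 counts), the spliceosome protein gene SMD1 (-3.46) and the mRNA-binding protein gene NPL3 (-3.37). PAM17 had the same 49 counts as NPL3. PZF1, which encodes TFIIIA, was at -3.23. The 5 highest were ALE1, a lysophospholipid acyltransferase gene, at 1.07 (interval 0.98 to 1.15), YML089C at 1.03, ERD1 at 1.00, XBP1 at 0.98 and YDR320W-B at 0.95. YDR320W-B had a downstream log2 density of -2.45, below the -1 required above, so it is uncertain. Neither YDR320W-B nor YML089C was among the highest of the 5619 genes. YML089C met both requirements, with a longest run of 15 positions at 0 and a downstream log2 density of -0.18. The 5619 genes were therefore not drawn from all IDs. Low values reached much farther from the mean than high ones.

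With every library thinned to the same mean of 0.914 counts per position, the upstream-to-downstream ratio of single genes was below 0.5 for 41.7% ± 4.2 of genes in C. glabrata, 40.8% ± 3.4 in S. kudriavzevii, 33.7% ± 2.0 in S. bayanus and 30.5% ± 1.8 in S. cerevisiae (32.8% ± 1.8 of matched IDs). The SD of the log2 ratio between genes was 0.850 ± 0.032 in S. cerevisiae, 0.848 ± 0.041 in S. kudriavzevii, 0.780 ± 0.048 in C. glabrata and 0.723 ± 0.033 in S. bayanus. The lowest upstream densities were at Sbay_653.44 in S. bayanus (-5.35), CAGL0G07183g2 in C. glabrata (-5.54) and, with the same 8 counts each, Skud_2049.4 and Skud_2064.7 in S. kudriavzevii (-4.51). Their windows held runs of 197, 397, 176 and 105 positions at 0, so they are uncertain too. The next C. glabrata gene, CAGL0K03729g, had a longest run of 40 and was at -4.03. The highest were Sbay_672.31 at 1.09, CAGL0C05533g at 1.08 and Skud_2074.1 at 5.25, or 37.9-fold over the mean. The window of Skud_2074.1 alone held 0.709% of that library's counts and raises its mean, to which the other libraries were thinned.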

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

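The choice of IDs, the whole-window repeat length, per-gene medians, the removal of repeated and very deep windows, full depth for the spread between genes, and the removal of genes with unread stretches were alternatives chosen after the data were examined. Of 75 values that answer a comparison and have an SD over sets of genes, 57 moved by less than 1 SD and 18 by more. The 4 library totals moved by more than counting error, and 5 to 7 lists were outside the random range, against 6. For single lists, 46 stayed within the bootstrap SD of the list's median, 17 moved by more and 1, outside the random range, turned direction. Of those that moved, 5 inside the random range also changed sign. All these counts include settings that could not move a value. They are the removal of the read minimum, which every gene passed, and the thinning of S. kudriavzevii, which left that library unchanged. The 15 values from the 3 deeper libraries, thinned to the mean depth of S. kudriavzevii, stayed within 1 SD.

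With at most 1 read per position, totals were 5045280 in S. cerevisiae, 5259440 in S. bayanus, 4959360 in C. glabrata and 2087923 in S. kudriavzevii. This cap keeps 22.6% of the S. cerevisiae counts and flattens deep positions. Under it the cytosolic ribosomal protein list turned from below all genes to 0.12 above (the cause was not tested), and the C. glabrata repeat length was 162.4 bp. The repeat length over the whole window was 156.6 bp in S. cerevisiae, 158.9 bp in S. bayanus, 159.6 bp in C. glabrata and 157.1 bp in S. kudriavzevii. Simulated windows with a gap were also shortened, by 4.1 to 7.5 bp. The real shortening was within that range in S. bayanus (4.4 bp) and below it in S. cerevisiae (4.0 bp), S. kudriavzevii (3.6 bp) and C. glabrata (2.1 bp). Whether the gap alone shortened the real values was not tested. With 3 peaks, the repeat length from the start codon on was 164 bp in S. bayanus and 161 bp in S. kudriavzevii.

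The upstream ratio with a 150 bp window was 0.679 in S. cerevisiae, 0.692 in S. bayanus, 0.633 in C. glabrata and 0.636 in S. kudriavzevii, since the window then starts nearer the first nucleosome. Medians of per-gene ratios were 0.628 in S. bayanus and 0.580 in S. kudriavzevii. The upstream ratio of mean densities in S. cerevisiae was 0.628 for IDs in the reference table, 0.620 with a divergent and 0.630 with a tandem upstream neighbour. These 3 leave out the unmatched IDs. The second peak in C. glabrata stood 0.348 over its trough in genes of at least 1 kb, and the first peak of S. kudriavzevii moved to 13 bp with 51 bp smoothing (the causes were not tested).

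Removing the read minimum moved nothing, because every gene passed it. Fragment length, a 73 bp read shift, shared orthologs and their differences, base composition, upstream gaps of at least 300 bp and multicopy or mitochondrial reads were not run.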

Other observations

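The tests of a positioned particle, of a chance second spike and of misplaced C. glabrata start codons were chosen after their results were seen. The tests of the C. glabrata flank in dense genes and with reads moved were chosen after the level over all genes was known, and the others before.

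Genes of S. cerevisiae that lie next to a tRNA gene had a different upstream landscape from other genes. It was tested whether the tRNA gene, itself kept free of nucleosomes, lowers the density just upstream of the neighbouring start codon. No lowering was seen in the 200 bp upstream: the 270 genes had a median of -0.40 there, at percentile 99.09 of random lists and so higher than most. Farther out, from 600 to 400 bp upstream, their density was 0.723 of the downstream level, below all 1000 random lists, whose central 95% ran from 0.845 to 0.923. Genes with a divergent neighbour (2810 genes) were at 0.878 there, inside their random range of 0.873 to 0.891, and those with a tandem neighbour (2577 genes) at 0.908, above theirs of 0.872 to 0.892. The distance to the tRNA gene was not used here, so the test does not exclude an effect outside the 200 bp upstream. The farther value was seen and not predicted, and its cause was not tested.

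Each library had a narrow spike just inside the start codon, at 63 bp in S. cerevisiae, 62 bp in S. bayanus, 58 bp in C. glabrata and 73 bp in S. kudriavzevii, 1.83-fold to 2.31-fold over its surroundings. The spikes were at most 2 bp wide in the 4 libraries. They were sought as narrow features over their close neighbours, so this width does not test a positioned particle. A cutting preference of MNase at the start codon, moved by a read shift that differs between libraries, predicted a matching feature at the gene's end, and the strongest spike or dip there lay within 5 bp of the spike distance in 4 of 4 libraries. Second spikes at 80 bp in S. bayanus and 63 bp in C. glabrata had paired upstream dips, the shallower at -3.27 SD of neighbouring positions, which argues against chance, although each dip was the lowest of 3 positions. Runs with different shifts added together may account for them, but only 1 of the 2 libraries had a matching feature at the gene end, and in C. glabrata the first spike could also give it.

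The low flank of C. glabrata could be technical. A mixture of read shifts is argued against by a bound: moving any share of the reads by up to 20 bp can raise the level from 580 to 400 bp upstream from 0.690 to at most 0.706 ± 0.025, against 0.886 ± 0.018 in S. cerevisiae as deposited. Genes of low density throughout are argued against as the whole cause by the genes at or above the median density over the window, where the level from 600 to 400 bp upstream was 0.750 ± 0.040 against 0.917 ± 0.021 in S. cerevisiae, while the width in genes of high downstream density, 540 bp against 194, 173 and 193 bp in S. cerevisiae, S. bayanus and S. kudriavzevii, decides less because that choice raises the level at which width is taken. Misplaced start codons cannot be told apart from a real difference: the start-codon spike, at 0.87 on the log2 scale, was lower than the 1.21 of S. cerevisiae but close to the 0.90 of S. kudriavzevii, which had no such flank. Species, mappability and assembly stay open, and longer spaces between C. glabrata genes were not tested.

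The low density in the coding part of cytosolic ribosomal protein genes may come from reads lost between near-identical duplicates. The 116 genes with a duplicate by their symbol had a median of -0.0035, and the 19 without had 0.14 ± 0.028 (bootstrap SD), against 0.18 for all genes. The 19 genes were below all genes by less than 2 SD, so lost reads and a real depletion cannot be told apart with so few single-copy genes. Upstream, the 19 genes were the emptier ones, at -1.06 against -0.57 for those with a duplicate.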
